A study of Mus musculus with 6 samples.

How the data were processed

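RNA was sequenced from cultured mouse leukaemia cells carrying the MLL-AF9 fusion oncogene, after infection with a lentivirus that encodes a non-targeting short hairpin RNA (shNT) or a hairpin against Atf3 (shAtf3). There were 6 libraries, 3 per group, and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol and a column, poly(A) RNA was enriched on oligo-dT beads, and libraries were made with a stranded kit. The deposited files hold whole-number counts per gene, 1 file per library, with the gene's position and length. Per the submitters' processing notes, HISAT2, HTSeq and DESeq2 were used with the mouse build mm10. Their versions, the annotation release and the strand setting of the counting were not given in the sources used here, so reads of overlapping genes on opposite strands cannot be assigned with certainty. How multi-mapping reads were counted was not given either, and counts of near-identical gene copies are uncertain.

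Each file listed 52636 genes, in the same order. Gene symbols were found for 52403 identifiers in the supplied name table, and 233 had none. Gene positions were compared with the GENCODE M21 annotation of GRCm38, the assembly behind mm10, after adding 1 to the start given in the files, and 95.2% of the matched genes had identical start and end. Total counts per library ran from 17782832 to 18962643. Intervals on counts cover counting error only, because reads without molecular identifiers are not independent molecules.

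Genes were filtered with filterByExpr, which left 14216, and libraries were scaled by TMM. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust dispersion and robust quasi-likelihood fit), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are shAtf3 against shNT on the log2 scale, with the standard error derived from the F statistic. Expression values (CPM, counts scaled to 1e6 per library) were computed from the deposited counts with TMM-scaled library sizes and are given as mean ± SD. No block was used, because the labels do not say that a replicate number marks a shared culture or day. The labels also do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

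The choice of 33 gene lists was fixed before the data were examined, as were the test, its alternatives and the rule for naming genes. The rule took Atf3. It took the 10 highest and 10 lowest fold changes among genes past the threshold, with groups that did not overlap in CPM and a mean of at least 5 CPM in the higher group. It took the next 5 genes in each direction by p, up to 3 risen and 3 fallen members of each list by p (up to 2 members, as values, where none passed), and 11 genes of serine, one-carbon and leukaemia biology. Genes with a predicted-gene symbol and pseudogenes were passed over. Not every gene the rule takes is reported. Pancreatic and haemoglobin genes, Rnu2-10 and Mir17hg are outside that rule and were chosen after their values were seen. Lists with at least 3 measured members, 31 in number, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it, as was camera on voom weights. Shares of counts were compared with exact two-sided permutation tests, for which 3 against 3 libraries cannot give a p below 0.1.

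Alternatives were DESeq2 size factors and upper-quartile factors in edgeR, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom, no low-count filter, a filter of at least 1 CPM in 3 libraries, a replicate block, and each library left out in turn. Alternatives chosen after seeing the data left out mitochondrial and structural RNA genes, kept protein-coding genes only, left out genes with a 3' UTR sequence described in the report, left out pancreatic and haemoglobin genes, or added a term for the batch of libraries that pancreatic transcripts mark. For that batch, 37 pancreatic genes were listed from general knowledge after the pattern had been seen, and a library with over 50 CPM of them was put in the batch. Ratios among the 22 with at least 50 counts were compared with 1000 random sets of tested genes matched on mean count.

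3' UTR sequences of the transcript with the longest coding sequence per gene came from GENCODE M21. For the 8580 genes with a log2 CPM of at least 3 and a 3' UTR, fold changes were regressed on UTR length and its square, GC content and its square, and expression. The residuals of genes with and without each of 15899 heptamers present in at least 50 UTRs were then compared as a z score, with 100 permutations of the residuals (Python 3.11.15, numpy 2.4.6).

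The steps were tested on simulated data. In counts drawn for the 14216 genes with 200 genes changed, edgeR recovered 42% of the genes changed 1.25-fold, 68% at 1.5-fold, 86% at 2-fold and 96% at 3-fold, 50 genes at each size. Of 161 calls, 15 were unchanged genes, or 9.32%, above the nominal 5%. These shares hold for 200 changed genes and do not describe the real comparison, where 50.3% of genes changed. Camera called the list shifted by -0.3 on the log2 scale and none of the others of the 31. Genes were drawn independently there, so false calls of lists with correlated genes were not tested. The heptamer scan returned a planted heptamer as the lowest in 10 of 10 simulations where 700 to 1000 genes held it, and in 9 of 10 where 300 to 500 did, at a planted shift of -0.1.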

Results

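Gene expression was measured by RNA-seq in mouse MLL-AF9 leukaemia cells, a model of acute myeloid leukaemia driven by a fusion of the MLL and AF9 genes. Cells had been infected with a lentivirus for a non-targeting hairpin (shNT, 3 libraries) or for a hairpin against Atf3 (shAtf3, 3 libraries). The shNT libraries held 17996874, 18106228 and 18305102 gene counts for replicates 1, 2 and 3, and the shAtf3 libraries held 17782832, 18962643 and 17944672. The single comparison of the design asks which transcripts differ after the Atf3 hairpin, and the series title names serine metabolism, nucleotide metabolism and the cell cycle as its subjects.

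Atf3 encodes activating transcription factor 3, a basic leucine zipper factor induced by stress. The gene (ENSMUSG00000026628) lies on chromosome 1 from 191170296 to 191218039, minus strand, in GRCm38. Its counts were 175, 131 and 138 in the shNT libraries and 178, 224 and 188 in the libraries labelled shAtf3. Atf3 was therefore higher, not lower, in the libraries labelled shAtf3, at 11.1 ± 0.952 CPM against 7.97 ± 1.33 CPM (SD, n = 3 each). The log2 fold change was 0.47 ± 0.12 (SE; adjusted p = 0.00145, edgeR), or 1.39-fold. The transcript level goes against the label, so every direction below is that of the libraries labelled shAtf3 and not of a measured loss of Atf3 transcript. The deposited files used here hold no protein values. The labels do not give the hairpin sequence.

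Of 14216 genes tested, 7145 changed at an adjusted p under 0.05 (edgeR), 50.3% of those tested. In the libraries labelled shAtf3, 3503 genes were higher and 3642 were lower. TMM scaling centres fold changes near 0, so these levels are relative, and a change in total RNA per cell would not be seen. A change of at least 2-fold was seen for 631 genes, 308 higher and 323 lower. The biological coefficient of variation was 5.34%, so small changes passed the test. Distances between libraries on log2 CPM were 1.63 times as large between groups as within groups, with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. The first principal component held 60.5% of the variance and separated the groups. The second held 15.6% and set shNT replicate 3 apart, at -29.5 against 13.97 and 8.97 for the other shNT libraries.

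**Figure D1:**
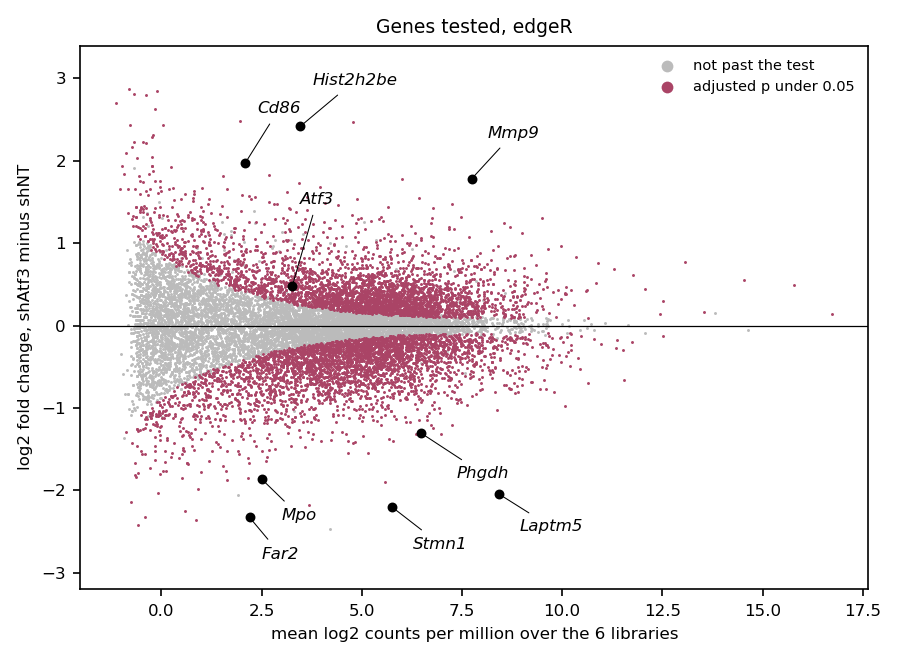
Each point is 1 of the 14216 genes tested, with its mean log2 CPM over the 6 libraries on the horizontal axis and its log2 fold change (shAtf3 minus shNT) on the vertical axis. Colour marks the 7145 genes past the adjusted p threshold, 3503 above and 3642 below 0 after TMM scaling, which centres fold changes near 0. Atf3 lies above 0 at 0.47.

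Transcripts of the pancreas were found in 4 of the 6 libraries. Counts of 37 pancreatic genes, listed after this was seen, summed to 63 and 109 in shNT replicates 1 and 2, against 5786 in shNT replicate 3 and 5159, 4115 and 2194 in the shAtf3 libraries. Ctrb1, a chymotrypsinogen, had 6 and 22 counts in shNT replicates 1 and 2 and 1469, 1300, 1082 and 537 in the other libraries. Haemoglobin transcripts followed, with 7 and 13 counts against 986, 935, 617 and 378. Pancreatic genes made up at most 0.0316% of a library's counts. Of the 27 pancreatic or haemoglobin genes tested, 0 changed between the groups by edgeR. That test could hardly call such genes, because the shNT libraries themselves ranged from 63 to 5786 summed pancreatic counts. It therefore does not decide whether these transcripts differ between the groups or affect the comparison. These transcripts split the libraries into a batch of 4, with shNT replicate 3 and all shAtf3 libraries, and the other 2, which are shNT only. With a term for this batch, 5416 genes changed (2632 higher, 2784 lower) and Atf3 kept a log2 fold change of 0.58 (adjusted p = 0.00773, edgeR). That fit compares shNT replicate 3 alone with the shAtf3 libraries and takes its spread from the others.

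**Figure D2:**
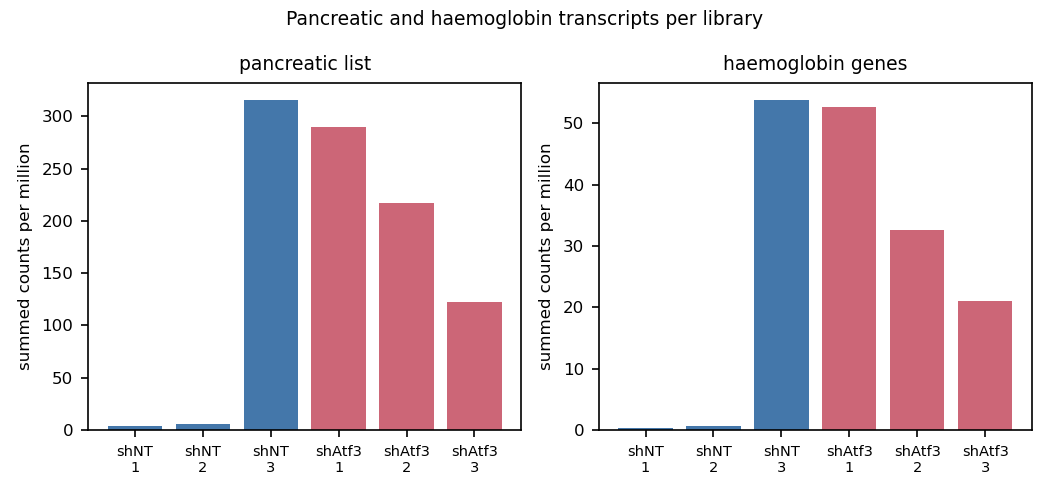
Bars give the summed CPM of the 37 pancreatic genes (left) and of the 4 haemoglobin genes (right) in each library, by group and replicate number. shNT replicates 1 and 2 held 3.50 and 6.02 CPM of pancreatic genes, and the other libraries 122 to 316.

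The largest increases in the libraries labelled shAtf3 included genes of myeloid cells and inflammation. Hist2h2be, a histone H2B gene, rose 5.34-fold, from 3.48 ± 0.149 to 18.6 ± 0.573 CPM. Cd86, a costimulatory ligand on antigen-presenting cells, rose 3.94-fold. Nlrp3, the sensor of an inflammasome, rose from 29.2 ± 1.20 to 100.3 ± 2.38 CPM, and Mmp9, a secreted gelatinase, from 96.5 ± 3.77 to 331.2 ± 18.7 CPM (log2 fold changes 1.78 ± 0.05 each, SE). Rin2, Pcdh17, Tmem268, Rdm1 and Rnf149 rose between 2.93-fold and 3.08-fold. Rdm1 and Rnf149 overlap other annotated genes that were tested, so their counts are less certain. The genes with the smallest p that followed were Il17ra, an interleukin-17 receptor chain, at 2.78-fold, the Src-family kinase gene Lyn at 2.36-fold, Slfn2 at 2.22-fold, the lectin gene Clec5a at 2.48-fold and the lysosomal protease gene Ctsd at 2.30-fold. Slfn2 and Hist2h2be belong to families of similar genes.

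Among the decreases, Laptm5, a lysosomal membrane protein of blood cells, fell from 554.7 ± 16.2 to 134 ± 5.66 CPM (log2 fold change -2.05 ± 0.04, SE; adjusted p = 5.04e-26, edgeR). Stmn1, which encodes the microtubule-destabilising protein stathmin, fell from 89.1 ± 5.11 to 19.3 ± 1.26 CPM, and Clec12a, a myeloid lectin receptor, from 75.3 ± 4.01 to 20.2 ± 0.965 CPM. Far2 had the largest drop among the genes the naming rule takes, at -2.33 ± 0.21, and overlaps Ergic2. The gene for myeloperoxidase, Mpo, fell from 8.63 ± 0.187 to 2.36 ± 0.175 CPM, and Atp7b, Steap3, Sytl1, Car12 and the proline synthesis gene Pycr1 had log2 fold changes of -1.60 to -1.85. The next genes by p were Hist1h1b, a linker histone, Rbbp4, a chromatin assembly subunit, the neutrophil elastase gene Elane, Phgdh, and Uhrf1, which maintains DNA methylation. The 3' UTRs of Laptm5, Stmn1, Clec12a, Rbbp4 and Uhrf1 contain the heptamer CTCACCA, and so does that of Il17ra, which rose. Genes with this heptamer were lower as a set, by 0.121 on the log2 scale over 960 genes after adjustment for UTR length, GC content and expression, and its z of -9.10 was below the lowest of 100 permutations, -5.005. The 3' UTR of Atf3 holds it within the octamer CTCACCAA, on chromosome 1 from 191171266 to 191171273. Without the genes that hold CTCACCA or TCACCAA, 5971 of 12399 genes changed, or 48.2%.

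Genes of serine synthesis fell. Phgdh, the first enzyme of serine synthesis from glycolytic intermediates (ENSMUSG00000053398, chromosome 3 from 98313170 to 98339990), fell from 125.7 ± 3.70 to 51.0 ± 2.18 CPM, a log2 fold change of -1.30 ± 0.05 (SE; adjusted p = 9.2e-20, edgeR). Psat1, the next enzyme, fell from 161 ± 5.64 to 80.3 ± 1.47 CPM, and Psph, which completes the pathway and overlaps Cct6a, from 21.9 ± 0.617 to 14.6 ± 1.82 CPM. The cytosolic and mitochondrial serine hydroxymethyltransferases Shmt1 and Shmt2 fell by 0.85 and 1.06 on the log2 scale. None of these 5 genes has CTCACCA in its 3' UTR. That bears only on a direct effect through this sequence, and indirect effects of the hairpin were not tested. Of 11 measured members of the list of serine and glycine synthesis and uptake, 9 fell and 2 rose, and the counts adjusted over the list alone were the same. The risen members were the transporter gene Slc38a2, at 0.38, and serine racemase, Srr, at 0.59. Srr overlaps Smg6 and Tsr1 and did not pass with the batch term (0.31, adjusted p = 0.109). Camera called the list lower (adjusted p = 0.00311), and with an estimated correlation the adjusted p was 0.203.

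Folate and nucleotide genes followed in part. In the folate one-carbon list 9 of 16 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.000774; adjusted p = 0.195 with an estimated correlation). Its median of -0.507 was -0.165 without the genes that hold CTCACCA or TCACCAA, where 6 of 13 fell (adjusted p = 0.00818). Mthfd2, the mitochondrial methylenetetrahydrofolate dehydrogenase, fell from 71.1 ± 3.76 to 34.8 ± 1.29 CPM and has CTCACCA in its 3' UTR. Mthfd1 and Mthfd1l fell by 0.74 and 0.67 on the log2 scale. In the purine synthesis list 13 of 17 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00193; adjusted p = 0.196 with an estimated correlation). Impdh2, Paics and Pfas had log2 fold changes of -0.62, -0.67 and -0.56, while Adssl1, one of the adenylosuccinate synthase genes, rose by 0.32. Of 21 genes of pyrimidine and deoxynucleotide synthesis 12 fell and 7 rose, with the same counts adjusted over the list alone, and camera did not call the list (adjusted p = 0.0745). It did with the batch term (adjusted p = 0.0348) and on voom weights (adjusted p = 0.0367), and not with an estimated correlation (adjusted p = 0.344) or without the genes that hold CTCACCA or TCACCAA (adjusted p = 0.0951). The ribonucleotide reductase genes Rrm1 and Rrm2 fell by 0.74 and 1.04, and thymidine kinase 1, Tk1, fell by 1.43, with the heptamer in its 3' UTR. Uck2, Ctps2 and Dguok rose by 0.29, 0.41 and 0.52, although the 3' UTR of Uck2 holds the heptamer too. In the pentose phosphate pathway 4 of 8 genes rose and 3 fell, without a call (adjusted p = 0.714), and here the median of 0.16 and the mean of -0.00130 differ in sign. Pgd rose by 0.36 and G6pdx, with CTCACCA in its 3' UTR, had a log2 fold change of -0.44.

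**Figure D3:**
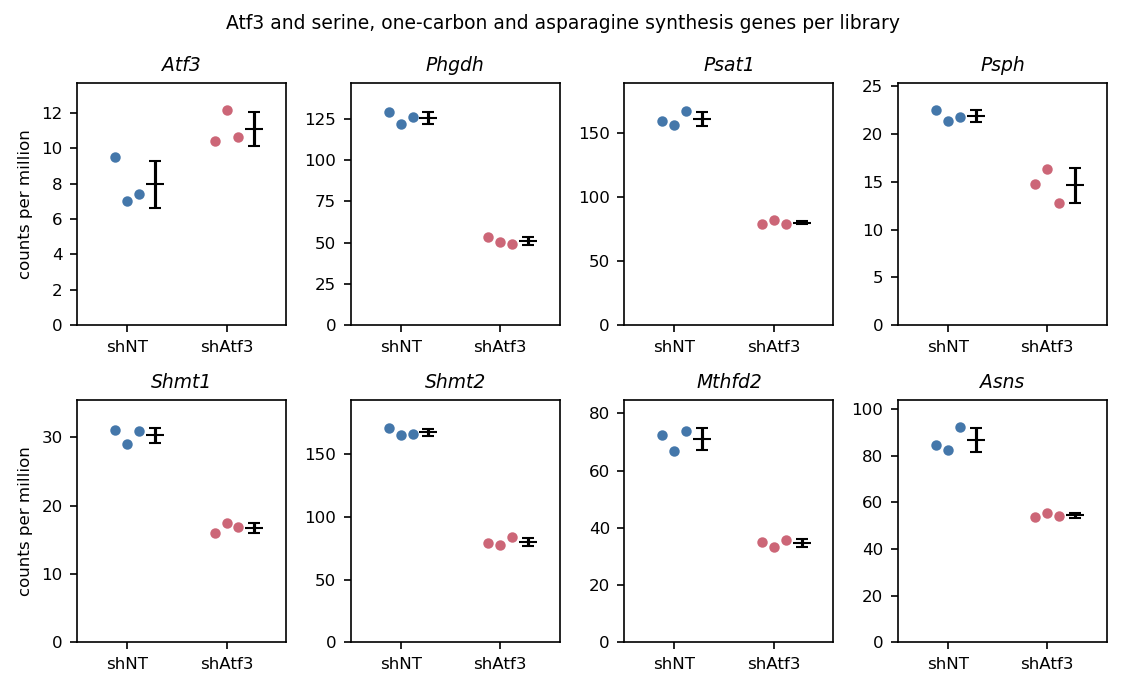
Points give CPM in each of the 3 shNT (left) and 3 shAtf3 (right) libraries, with the mean and SD beside them, for Atf3, Phgdh, Psat1, Psph, Shmt1, Shmt2, Mthfd2 and Asns. Atf3 is higher in the libraries labelled shAtf3 and the other genes are lower, with no overlap between groups.

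Cell cycle genes fell together in the libraries labelled shAtf3. In the list of G1/S and DNA replication genes 29 of 30 fell, also when adjusted over the list alone, with a median log2 fold change of -0.89 (camera adjusted p = 2.43e-15; adjusted p = 0.0790 with an estimated correlation). The replicative helicase genes Mcm5 and Mcm7 fell by 1.32 and 1.15 on the log2 scale. In the list of G2/M and mitosis genes 24 of 28 fell, 26 when adjusted over the list alone, with a median of -0.62 (camera adjusted p = 8.84e-10; adjusted p = 0.105 with an estimated correlation). Top2a, Kif11 and Hmmr had log2 fold changes of -0.72, -0.80 and -0.90. Histone transcripts took 0.456 ± 0.000747% of counts in shNT and 0.249 ± 0.00784% in shAtf3 (exact permutation p = 0.1, the smallest possible; 0.156 after Benjamini-Hochberg adjustment over 14 measures). Of 61 clustered histone genes 56 fell and 1, Hist2h2be, rose. Poly(A) RNA had been enriched, yet mitochondrial, ribosomal and small structural RNA together took 25.2% of counts in shNT and 28.3% in shAtf3. How far the histone share depends on RNA that escaped this selection was not tested. Cdk inhibitors and G1 cyclins went both ways, with 3 of 14 risen and 6 fallen, also when adjusted over the list alone (camera adjusted p = 0.457). Cdkn1b, which encodes p27, rose by 0.55, and Rbl1 and Cdk2 had log2 fold changes of -0.57 and -0.40.

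Genes of MYC and ribosome biogenesis fell in 23 of 24 cases, also when adjusted over the list alone (camera adjusted p = 2.4e-08; adjusted p = 0.105 with an estimated correlation). Npm1, the nucleolar protein nucleophosmin, fell from 886.5 ± 18.5 to 521.2 ± 20.7 CPM, Mybbp1a and the spermidine synthase gene Srm had log2 fold changes of -0.85 and -1.02, and Myc itself fell from 179 ± 4.82 to 141 ± 2.58 CPM. Of the cytosolic tRNA synthetase genes 15 of 19 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 8.33e-05; adjusted p = 0.203 with an estimated correlation). Vars, Farsb and Yars fell by 0.90, 0.76 and 0.65 on the log2 scale. Among ATF4 targets of the amino acid stress response 12 of 19 fell and 5 rose, 13 and 5 when adjusted over the list alone (camera adjusted p = 0.0249; adjusted p = 0.344 with an estimated correlation). Asparagine synthetase, Asns, fell from 86.6 ± 5.14 to 54.5 ± 0.961 CPM and the amino acid transporter genes Slc7a1 and Slc7a5 had log2 fold changes of -0.82 and -0.67, whereas Slc7a11, the cystine transporter, rose by 0.66 and Cebpg by 0.54. In glycolysis 10 of 17 genes fell, 11 when adjusted over the list alone, and 0 rose (camera adjusted p = 0.00496; adjusted p = 0.479 with an estimated correlation), with Gpi1, Pfkl and Ldha at -0.70, -0.74 and -0.49. Gpi1 and Pfkl hold CTCACCA in their 3' UTRs. Without genes that hold it or TCACCAA, the ATF4 target list (median -0.254 against -0.247 with them; adjusted p = 0.0951) and glycolysis (median -0.109 against -0.153; adjusted p = 0.0790) were not called.

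Of 18 p53 targets 9 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0189; adjusted p = 0.195 with an estimated correlation). Plk3 and the antiproliferative gene Btg2 rose by 0.83 and 0.81 and Trp53inp1 by 0.48. Cdkn1a, which encodes p21, was at 0.15 (adjusted p = 0.00534), and its call ended with the batch term (0.08, adjusted p = 0.336) and without shNT replicate 2 (0.12, adjusted p = 0.0601). In the Bcl2 family 6 of 10 genes rose and 2 fell, also when adjusted over the list alone, without a call of the list (adjusted p = 0.125). The genes of the pro-apoptotic proteins Bim, Bcl2l11, and Bmf rose by 1.08 and 0.79, and that of the anti-apoptotic protein Mcl1 by 0.51. Bcl2l11 rose although its 3' UTR holds CTCACCA.

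Inflammatory genes and monocyte markers rose. In the inflammatory and NF-kB list 15 of 18 rose and 1 fell, also when adjusted over the list alone, with a median of 0.71 (camera adjusted p = 5.71e-07; adjusted p = 0.195 with an estimated correlation). The chemokine genes Cxcl2 and Ccl3 rose 2.90-fold and 1.77-fold, and Ccl5, at a few CPM, was lower at -0.98 and lost its call without shNT replicate 3 (-0.78, adjusted p = 0.0537). Of 17 monocyte and macrophage markers 12 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 3.91e-05; adjusted p = 0.195 with an estimated correlation). Lyz2, which encodes lysozyme and has the close copy Lyz1, rose from 414 ± 27.2 to 1023 ± 35.3 CPM, and the chemokine receptor gene Ccr2 rose by 0.78. Neutrophil genes divided, with 8 of 20 risen and 10 fallen, also when adjusted over the list alone, and no call (adjusted p = 0.671). The granule protease genes Elane, Ctsg and Prtn3 fell by 0.98, 0.56 and 0.54, and Mmp9, Ly6g and S100a9 rose 3.43-fold, 2.11-fold and 1.90-fold. Of 12 dendritic cell and antigen presentation genes 6 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0592), and the list passed without shNT replicate 1 (adjusted p = 0.0470) or 3 (adjusted p = 0.0352), with the filter of 1 CPM (adjusted p = 0.0422) and on voom weights (adjusted p = 0.0427). It did not with an estimated correlation (adjusted p = 0.479) or without the genes that hold CTCACCA or TCACCAA (adjusted p = 0.0957). Itgax and Cd74 rose by 1.09 and 1.04.

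**Figure D4:**
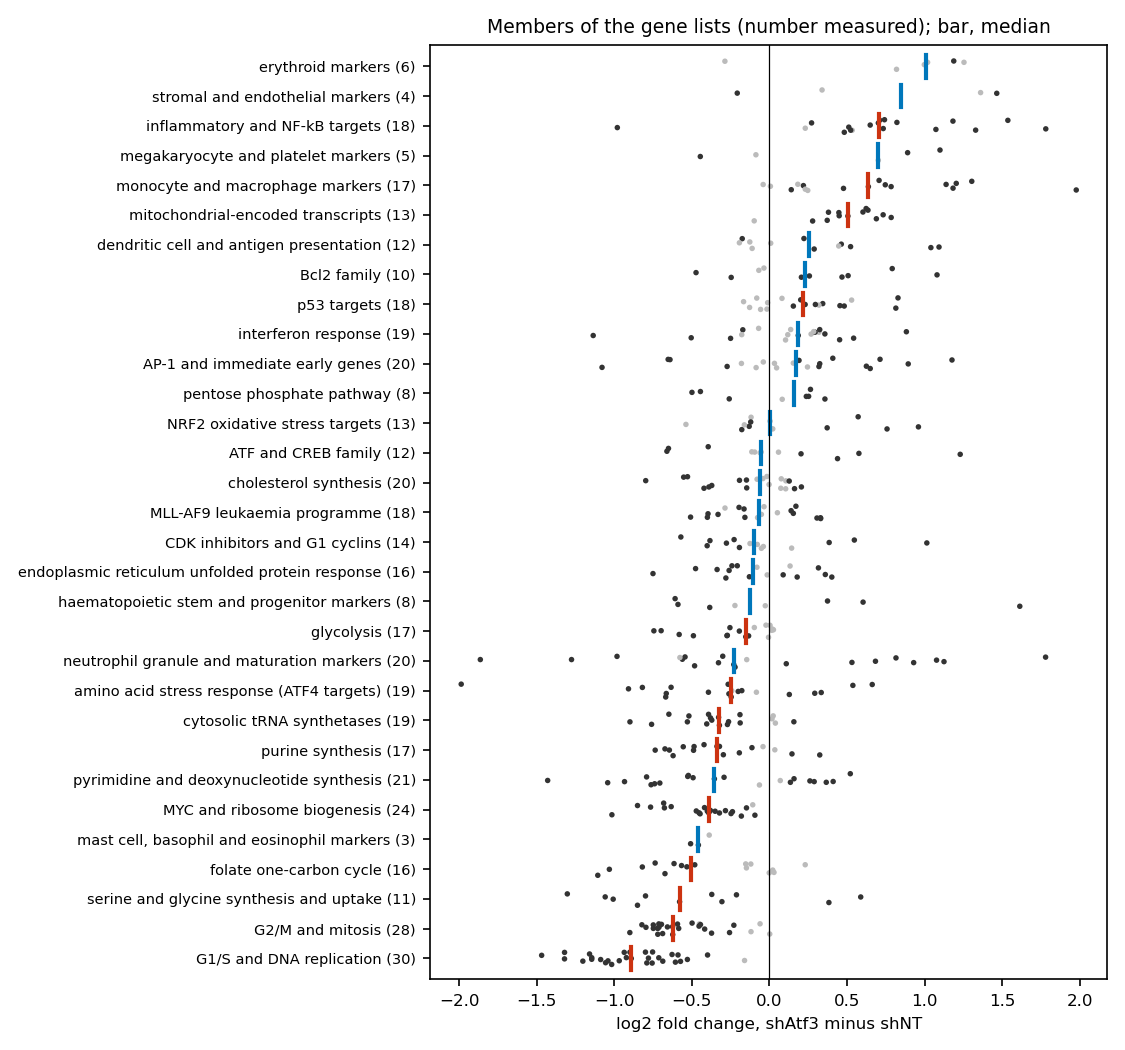
Each row is 1 of the 31 gene lists tested, with the number of measured members in brackets. Points give the log2 fold change of each member (dark, past the edgeR test; grey, not), bars give the median, red where camera called the list and blue where not; G1/S and DNA replication has the lowest median, -0.89.

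In the MLL-AF9 leukaemia programme 6 of 18 genes rose and 7 fell, also when adjusted over the list alone, with a median of -0.0644. Camera, which compares the list with other genes, did not call it (adjusted p = 0.455), and fry, which does not, did (adjusted p = 0.00586). Hoxa9 was at 90.4 ± 4.76 CPM in shNT and 85.8 ± 2.81 CPM in shAtf3 (adjusted p = 0.190, edgeR), and its cofactor Meis1 was at -0.16 (adjusted p = 0.00262), without a call under the batch term (-0.14, adjusted p = 0.0841). Myb, Runx2 and Pbx3 had log2 fold changes of -0.51, -0.40 and -0.33, and Jmjd1c and Hoxa7 rose by 0.33 and 0.31. Of 8 measured stem and progenitor markers 3 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.890; median -0.12, mean 0.0948). Runx1 rose by 0.60 and Kit fell by 0.61.

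Stress and signalling lists went both ways. Of 20 AP-1 and immediate early genes 9 rose and 4 fell (camera adjusted p = 0.0917), and the list passed without shNT replicate 1 (adjusted p = 0.0479) and on voom weights (adjusted p = 0.0465). With an estimated correlation the adjusted p was 0.57, and without the genes that hold CTCACCA or TCACCAA the median went from 0.172 to 0.0276, with 5 risen and 4 fallen (adjusted p = 0.538). Dusp6, Ier3 and Fosl2 rose by 1.18, 0.89 and 0.65, and Dusp2, Fosb and Jun had log2 fold changes of -1.08, -0.65 and -0.64. In the ATF and CREB family 4 of 12 rose and 3 fell (adjusted p = 0.956; median -0.06, mean 0.0397), with Creb5 risen by 1.23. Of 16 genes of the unfolded protein response of the endoplasmic reticulum 5 rose and 8 fell (adjusted p = 0.422), 6 and 9 when adjusted over the list alone. Of 19 interferon response genes 7 rose and 4 fell (adjusted p = 0.188), 8 and 4 when adjusted over the list alone. Of 13 NRF2 targets 4 rose and 3 fell (adjusted p = 0.566), among them Fth1 and Gsr, which rose by 0.96 and 0.76. Of 20 cholesterol synthesis genes 3 rose and 9 fell (adjusted p = 0.278), 5 and 9 when adjusted over the list alone, with Msmo1 at -0.80. The counts of the AP-1, ATF and CREB, and NRF2 lists adjusted over the list alone equalled those over all genes.

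Mitochondrial transcripts took a larger share of the libraries labelled shAtf3, at 10.2 ± 0.852% of counts against 7.55 ± 0.398% (exact permutation p = 0.1, the smallest possible; 0.156 after adjustment). Mitochondrial ribosomal RNA rose from 6.78% to 9.18% and mitochondrial mRNA from 0.766% to 1.001%. Without the 10 most abundant genes the rise in the share was 0.374 percentage points, against 2.64. The share in shNT replicate 3, which held pancreatic transcripts as the shAtf3 libraries did, was 7.96%, below the lowest shAtf3 library at 9.33%. Of 13 mitochondrial-encoded transcripts 12 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 9.75e-05; adjusted p = 0.438 with an estimated correlation), with mt-Cytb at 0.73 and mt-Nd5 at 0.63. Mitochondrial, ribosomal and small structural RNA together took 25.2 ± 0.422% of counts in shNT and 28.3 ± 0.786% in shAtf3, the nuclear RNA Malat1 0.651 ± 0.0313% and 1.06 ± 0.0262%, and protein-coding genes 72.6 ± 0.369% and 69.4 ± 0.793%, so the make-up of the libraries differs with the groups (exact permutation p = 0.1 each). Ribosomal protein genes took 5.54 ± 0.0831% of counts in shNT and 4.91 ± 0.103% in shAtf3 (exact permutation p = 0.1).

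Markers of other cell types were few. Of 12 erythroid markers 6 were measured and 1, Car2, rose, also when adjusted over the list alone (camera adjusted p = 0.190), with a median of 1.01 set by the haemoglobin genes. Without shNT replicate 3 the median was 5.31 (adjusted p = 0.00332), because the remaining shNT libraries held almost no haemoglobin counts. Of 3 measured mast cell, basophil and eosinophil markers 2 fell (adjusted p = 0.174), of 5 megakaryocyte and platelet markers 2 rose and 1 fell (adjusted p = 0.457; 3 and 1 adjusted over the list alone), and of 4 stromal and endothelial markers 1, Acta2, rose and 1 fell (adjusted p = 0.455). The counts of the mast cell and stromal lists adjusted over the list alone were the same. None of 12 B cell markers passed the count filter. Of 12 T and NK cell markers only Lck did, at 2.64 ± 0.277 CPM in shNT and 1.45 ± 0.218 CPM in shAtf3 (adjusted p = 0.00320, edgeR), and neither list was tested.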

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

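Settings that leave out gene classes, drop the pancreatic and haemoglobin genes or add a batch term were chosen after seeing the data, and the others before the data were examined. Over the 18 alternatives the number of genes changed ran from 5416 (batch term) to 7221, against 7145, and no gene called in both changed sign. DESeq2's Wald test called 6190 genes and limma-voom 7055. Leaving out 1 library gave 6457 to 6777 genes. Atf3 stayed higher in the libraries labelled shAtf3 in each alternative that kept the gene (the fit without genes that hold the 3' UTR site left it out), at 0.39 to 0.62, with adjusted p of at most 0.0196. Genes changed at least 2-fold ran from 456, among protein-coding genes, to 735 without a low-count filter. Camera called 13 lists, none (0) with an estimated correlation, where G1/S came closest at an adjusted p of 0.0790, and fry 26, a test that does not compare a list with other genes; the other alternatives run for lists gave 11 to 16, and upper-quartile factors, no low-count filter, protein-coding genes only and removal of pancreatic and haemoglobin genes were not run for lists. The ratio of distances was 1.51 to 1.77 with 1 library left out, against 1.63. Without the 10 most abundant genes, which include the mitochondrial ribosomal RNAs, the rise in the mitochondrial share was 0.374 percentage points, against 2.64, and the drop in the histone share was -0.2617 points, against -0.208; the first follows from the genes left out. Of 169 named genes past the test, 21 lost the call under at least 1 alternative: 19 with the batch term, 12 with a library left out and 4 under others, and 0 reversed. The largest main change among them was 1.01. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.109, -0.0304 and -0.20, and no library correlated best with its own number. A replicate block gave 6739 genes and 13 lists. With 3 libraries per group, the smallest simulated changes were recovered for 42% of genes. The shift of genes with CTCACCA, -0.121, was -0.120 over all tested genes with a UTR, -0.153 at 32 CPM or more, and -0.113 with the longest UTR per gene, settings chosen after seeing the data.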

Other observations

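Tests of the Atf3 count and label exchange, of UTR length, of the pancreatic transcripts, and of gene counts over other splits were chosen after those results were seen; the tests of listed genes, of site length and of gene lists over other splits were written before.

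Among pancreatic transcripts, the 22 pancreatic genes with at least 50 counts varied in their ratios across the 4 libraries with a chi-square per degree of freedom of 1.57 (1.708 over the 3 shAtf3 libraries alone). The median of 1000 random sets of genes matched on count was 1.644 over the 3 shAtf3 libraries and 5.17 over the same 4 libraries. The value of 1.57 lay just under 1.644, but it covers 4 libraries and the sets 3. Over the 3 shAtf3 libraries alone, 1.708 lay above 1.644, and 43.1% of the sets were as low as 1.57. Sets over the 4 libraries span both groups, between which many genes changed. Whether the RNA came from a single source is therefore not decided. Transcription by the leukaemia cells after the Atf3 hairpin is argued against, since shNT replicate 3 held 1.51 times the mean level of the shAtf3 libraries. How far a batch of libraries marked by these transcripts lies behind the genes changed cannot be decided. With the batch as a term, the group effect rests on shNT replicate 3 alone against the shAtf3 libraries. A batch effect and a trait of that library cannot be told apart. In that fit 99.94% of the main calls kept the sign of their log2 fold change. Whether the RNA entered during handling or the reads were assigned to the wrong library in sequencing was not tested, and the small nuclear RNA gene Rnu2-10, with 26 and 91 counts in shNT replicates 1 and 2 against 720 to 979 elsewhere, follows the same division.

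Atf3 was higher in the libraries labelled shAtf3. Counting noise is argued against: summed counts were 590 against 444, and their ratio after scaling by TMM library size was 1.39, with an exact 95% interval of 1.23 to 1.58. An exchange of the 2 group labels is argued against by the sequence CTCACCAA in the Atf3 3' UTR, since 114 of 220 genes with it fell and 44 rose in the libraries labelled shAtf3 (1874 and 1946 of 6024 genes without a site), and only 2.31% of 2684 UTRs within 20% of its length (1189 bases) hold it. This test rests on the sites being those of the hairpin, whose sequence the labels do not give. Whether the hairpin lowered ATF3 at all cannot be told from these counts. If it did, open explanations, not tested here, include repression of translation without loss of transcript and release of ATF3 from repressing its own gene. Reads from transcript ends the hairpin leaves intact are another.

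Genes with CTCACCA in their 3' UTR were lower in the libraries labelled shAtf3, and a candidate explanation is silencing of other transcripts through the hairpin's seed. Median log2 fold changes were -0.168 for 220 genes with the 8-base site CTCACCAA, -0.0715 for 740 with CTCACCA alone, -0.0442 for 429 with TCACCAA alone, 0.0174 for 1167 with the 6-base site and 0.00863 for 6024 without a site. The order was the predicted one except between the last 2 classes, which differ by less than the standard error of 0.0109. CTCACCA and TCACCAA were the 2 lowest heptamers of the scan on these same fold changes. That the classes holding them lie below the genes without a site therefore largely follows from this choice, and so may their order. The step between the 6-base site and no site was not fixed by it and was not in the predicted direction. The classes are therefore not separate support for silencing through the seed. CTCACCA was the lowest of a scan already adjusted for UTR length, GC content and expression. Genes with it had a mean of -0.109, against -0.0242 for the lowest of 1000 matched random sets, which is therefore not separate support. The scan itself argues against these features, as fitted, as the whole cause. Its z was -9.10, and the lowest of any heptamer in 100 permutations was -5.005. Without all listed genes the shift was -0.116, but 918 of the 960 genes with the heptamer were left. The listed genes therefore do not carry the shift, while related genes outside the lists were not tested. If silencing through the seed holds, the drops of Laptm5, Stmn1 and Clec12a may be effects of the hairpin's seed and not of Atf3. Indirect effects of such silencing on genes without the site, those of serine synthesis among them, were not tested. A response of the cells through an endogenous regulator with this site was not tested, and a further hairpin was not analysed here.

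Among the heptamers of the same scan, none lay above the highest permuted z of 4.76. The highest was TGCAATA, at 4.48 over 794 genes, which overlaps the miR-92 site GTGCAAT. Sites of the miR-19, miR-92 and miR-17 families had z of 3.94, 3.51 and 3.16, and that of miR-18 had -0.413. Mir17hg, a host transcript of miRNAs of these families, was at 0.02 (adjusted p = 0.853, edgeR). Other host transcripts were not compared with these sites.

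The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 7145 genes changed, 3503 higher and 3642 lower, with 631 changed at least 2-fold, and the highest other split gave 1 for each, with either side of a split taken as shAtf3, since its direction is arbitrary. For gene lists called by camera the real split gave 13 and the others 4 to 10, so lists were also called in splits that mix the groups. In each case 1 of the 10 splits, the real one, gave a value as large.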
